A study of Mus musculus with 2 samples.

How the data were processed

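Droplet-based 3' single-cell RNA sequencing (10x Genomics Chromium) was measured in ventricular cells of neonatal C57/BL6 mice, in 1 library from sham-operated hearts (the chest opened only) and 1 library from hearts whose apex had been resected in the same operation. Each library held the cells of 4 hearts taken 2 days after surgery, pooled by surgical condition before dissociation. Per the submitters' sample descriptions, hearts were perfused, digested with dispase, collagenase and DNase, strained, treated with a red-cell lysis buffer and depleted of dead cells. Strainers and digestion favour small cells, so the class shares describe the suspension and not the tissue.

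The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, for 32285 genes per library. Per the submitters' processing notes, reads were processed with Cell Ranger (version not given) against genome build GRCm38, and the matrices used here are the filtered ones that hold only barcodes called as cells. The lowest total per barcode was 500 UMIs in both libraries. The other deposited columns are cell barcodes and gene identifiers. Of the genes, 32158 were matched by Ensembl identifier to a GRCm38 annotation, which gave the positions printed in the report.

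Cells were kept with 500 or more genes, 1000 or more UMIs and 20% or less mitochondrial counts. Doublets were scored per library with the Scrublet method in scanpy, with an expected rate of 0.8% per 1000 barcodes. Where the automatic threshold marked under 0.5% of cells, the highest scores up to the expected rate were removed instead. In the main run the automatic threshold marked 18.0% of sham cells and 7.9% of resected cells, against expected rates of 11.7% and 9.2%. Counts of both libraries were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen per library, were reduced to 30 principal components, and a graph of 15 neighbours was clustered by the Leiden method at resolution 1 without integration of the libraries. This gave 28 clusters. Each cluster took the class with the highest mean marker score out of 19 marker lists, if that score was at least 0.5 and at least 3 of the class's markers were seen in 10% of its cells. Clusters with a second unrelated class scoring at least 1.5 and at least 0.5 times the best score, or whose 10 leading genes held more markers of another class, were left unnamed and out of the class comparisons. Macrophage and monocyte clusters were joined, as were pericytes and smooth muscle (mural cells). Class names are assignments from RNA, and "epicardial" in the text stands for cells with an epicardial marker profile.

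Counts were summed over the cells of a class and library and scaled to a sum of 1000000 UMIs (CPM). A sum has an exact Poisson interval, a share an exact Clopper-Pearson interval, and a ratio of 2 sums the exact conditional binomial interval, all at 95%. These intervals cover counting error only. With 1 pooled library per group, no test, standard error or p-value was computed from cells, and no count of changed genes is given. Every comparison is therefore a difference between 2 libraries that no replicate can check, and differences of surgery, pool, litter, sex composition and library preparation are confounded. A count of 0 in a class and library was given a floor of 3 counts, and "at least" marks a fold against that floor. The floor is a one-sided limit, so the lower bound of the 95% interval of the same ratio is lower and stands beside each such fold.

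For the share of cells with a UMI of a gene, each cell was thinned at random to 2000 UMIs, and cells with fewer were left out. Endocardial cells served as the background class for C3. Depth differed between the libraries. Sham held 28173318 UMIs over 14624 barcodes and the resected library 34824955 over 11532. Of these, 64.1% of sham and 79.3% of resected barcodes passed the filter, so the UMI minimum removed proportionally more of the sham library. After doublet removal 7692 sham cells with 16558729 UMIs and 8429 resected cells with 27489900 UMIs remained, at medians of 1732 and 2567 UMIs per cell. The precision of a CPM value follows from the class sums, which ranged in the main comparisons from 583361 UMIs (resected vascular endothelial) to 9227544 (resected fibroblast).

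20 gene lists were written before the data were examined, as were the filters, the rule for named genes and most alternatives. The lists were complement components, complement receptors and regulators, epicardial identity, epithelial to mesenchymal transition, secreted growth factors, matrix and fibroblast activation, cytokines and chemokines, acute phase and NF-kB or STAT3 response, interferon-stimulated genes, proliferation, hypoxia and glycolysis, fatty acid oxidation, mature sarcomere and calcium handling, fetal and stress cardiomyocyte genes, angiogenesis and endothelial tip, resident macrophage, inflammatory and repair macrophage, dissociation stress, haemoglobin, and sex-linked genes. Several genes sit on more than 1 list. For each class with 50 or more cells in each library, a list's value is the median log2 ratio of CPM (resected over sham) over members with 20 or more UMIs in both libraries together. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test. A 95% interval of the median, taken from the ordered members, describes the spread among a list's genes, and no direction is given to a list whose interval holds 0. Members at least 1.5-fold higher or lower were counted. The lists hold genes that mark classes, and a class's own markers were not used as results for that class except where the list itself is compared between libraries.

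Genes named singly were chosen by rule. In each class, genes with 20 or more UMIs in both libraries together and 50 or more CPM in the library where they are higher were ranked by the bound of the ratio's interval nearest to 1, separately for higher and lower. Mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked genes, and gene models named only by a number, were left out. The first 12 in each direction were eligible in the epicardial class, the first 8 in the fibroblast, macrophage or monocyte, vascular endothelial and cardiomyocyte classes, and the first 3 in the others. The first 4 members of each list, ranked by the same bound, could be named as well, and C3, C3ar1, C5ar1, Cfb and Wt1 were reported whatever their values.

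The alternatives were a looser filter (200 genes, 500 UMIs, 40% mitochondrial counts), a stricter filter (1000 genes, 2000 UMIs, 10%), all doublets kept, resolutions 0.5 and 2, each library clustered alone, scaling by the median log ratio of expressed genes, a class total without mitochondrial, ribosomal protein and haemoglobin genes, the mean of per-cell CPM, cells thinned to 2000 UMIs before summing, list members with 1 or more and with 100 or more UMIs, and shares of cells thinned to 1000 UMIs or unthinned. Another 4 were chosen after seeing the data. These were the expected doublet rate removed in both libraries, the complement genes left out of clustering, macrophage and monocyte clusters kept apart, and the macrophage or monocyte and neutrophil classes joined.

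The ratio, list and thinning code was tested on simulated data with the depth of the epicardial class. For ratios and lists, each gene was drawn as an independent Poisson count, with no variation between cells, clusters or hearts. The simulation therefore checks the code, and not how the intervals or percentiles hold in these data. Of 10737 genes simulated with no difference, 95.7% of intervals held a ratio of 1. For simulated folds of 0.5 and 2, 83.9% and 81.8% of intervals lay past 1, and for folds of 0.25 and 4 all did (100.0%). Of 500 simulated lists of 12 unchanged genes, 4.0% lay under percentile 5 and 5.0% over percentile 95, and a list with a simulated fold of 2 gave a median log2 ratio of 0.98. Analyses used Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Cell cycle phases, pseudotime and ligand to receptor scores were not used here.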

Results

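Single-cell RNA profiles of ventricular cells from neonatal mouse hearts were compared between 1 sham-operated library and 1 library made after apical resection, an operation that removes the tip of the left ventricle at an age when mouse hearts can still regenerate. Each library pooled 4 hearts collected 2 days after surgery. The sample titles give postnatal day 2, while the series design gives surgery on postnatal day 0 or 1, so the age at collection is open between day 2 and day 3. The sham library held 14624 cell barcodes with 28173318 UMIs in all, a median of 1483 UMIs and 815 genes per barcode, and a median mitochondrial share of 5.45%. The resected library held 11532 barcodes with 34824955 UMIs, a median of 2297 UMIs and 1127 genes, and a mitochondrial share of 3.86%. After filtering and doublet removal, 7692 sham and 8429 resected cells were compared. Cells of the resected library remained deeper, at a median of 2567 UMIs against 1732. There is no replicate library, so every value below describes a difference between 2 libraries, and the 95% intervals in parentheses cover counting error only.

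The first comparison asked which cells the 2 suspensions contained. Fibroblasts were the most abundant class in both, with 38.08% (36.99 to 39.17) of sham cells and 37.50% (36.47 to 38.55) of resected cells. Myeloid cells were more abundant after resection. The macrophage or monocyte class held 4.99% of sham and 10.51% of resected cells, a ratio of 2.11 (1.87 to 2.38), and neutrophils held 0.48% and 5.37%, a ratio of 11.2 (7.98 to 16.1). The myeloid classes combined made up 5.47% (4.98 to 6.01) and 15.89% (15.11 to 16.68) of cells. Epicardial cells, the mesothelial layer that covers the heart, made up 6.11% (5.59 to 6.67) of sham and 10.37% (9.73 to 11.04) of resected cells, a ratio of 1.70 (1.52 to 1.90). Vascular endothelial cells were less abundant after resection, at 5.90% against 2.08% and a ratio of 0.352 (0.294 to 0.420). Cardiomyocytes, of which the dissociation recovers mainly small or fragmented cells, held 7.05% and 5.62%, endocardial cells 13.12% and 11.95%, valve interstitial cells 8.19% and 6.83%, and mural cells 2.03% and 2.42%. Lymphatic endothelial cells held 0.43% and 0.47%, B lymphocytes 0.46% and 0.38%, erythroid cells 1.39% and 0.61%, and mast cells 0.14% and 0.56%. Red-cell lysis acts on the erythroid share.

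Unnamed clusters held 11.64% of sham and 5.33% of resected cells, which affects the shares of the named classes. The largest of them carried genes of both capillary endothelium and pericytes in 452 sham and 143 resected cells, so the endothelial share also depends on how these are counted. The others combined fibroblast with cardiomyocyte genes (307 and 157 cells, and 78 and 32 cells) or dendritic with T lymphocyte genes (58 and 117 cells). The UMI minimum removed more sham than resected barcodes. With the stricter filter the ratio was 0.210 for vascular endothelial cells, 0.450 for cardiomyocytes, 1.36 for fibroblasts and 4.06 for neutrophils, and the valve interstitial ratio moved from 0.834 to 1.12. With each library clustered alone the cardiomyocyte ratio was 1.22, the fibroblast ratio 1.90, the neutrophil ratio 1.87, the macrophage or monocyte ratio 3.48 and the vascular endothelial ratio 0.695.

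**Figure D1:**
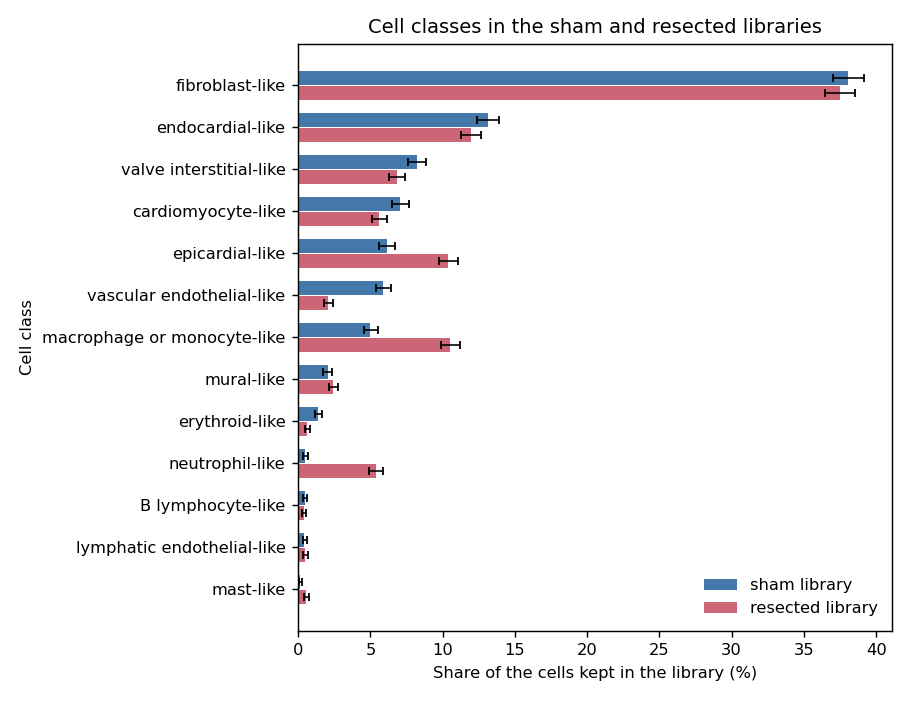
Share of cells per class (x axis, percent of the cells used) in the sham and resected libraries, drawn as bars with lines for 95% Clopper-Pearson intervals that cover counting error only. Epicardial cells lie at 6.11% and 10.37%, macrophages or monocytes at 4.99% and 10.51%, neutrophils at 0.48% and 5.37%, and vascular endothelial cells at 5.90% and 2.08%.

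The series concerns epicardial complement C3, the central protein of the complement cascade, which is cleaved into an opsonin and the signalling peptide C3a. C3 (ENSMUSG00000024164, GRCm38 chromosome 17, 57203970 to 57228136, minus strand) was measured in every class. Epicardial cells were its main source in both libraries. They held 97.15% of all C3 UMIs in the sham library and 76.94% in the resected library. Summed over all cells, C3 was higher after resection, at 455 CPM in sham and 607 CPM in resected cells, a ratio of 1.33 (1.30 to 1.37). Within the epicardial class it was lower relative to the class total. Epicardial cells had 5539 CPM (5412 to 5667) in sham, from 7322 UMIs, and 2577 CPM (2533 to 2622) after resection, from 12831 UMIs, a ratio of 0.465 (0.452 to 0.479) and a log2 ratio of -1.10. With each cell thinned to 2000 UMIs, 98.85% (96.69 to 99.76) of 262 sham epicardial cells held a C3 UMI, with 208 cells too shallow to include. After resection the share was 83.17% (80.41 to 85.69) of 808 cells, with 66 left out. Without thinning the shares were 99.36% and 92.11%, at median depths of 2106.5 and 4613.5 UMIs. In the epicardial cluster with most sham cells, formed without complement genes, the ratio of C3 CPM was 0.712 (0.690 to 0.735). That cluster held 7201 C3 UMIs in 447 sham cells and 8287 in 413 resected cells. C3 UMIs per cell were thus not lower there, in a library with deeper cells. In endocardial cells, taken as background, 0.777% of thinned sham cells and 1.87% of thinned resected cells held a C3 UMI (0.595% and 2.28% unthinned, at median depths of 1637 and 2084 UMIs).

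C3 in fibroblasts and macrophages was higher after resection. Fibroblasts had 11.1 CPM in sham and 285 CPM (274 to 296) in resected cells, a ratio of 25.7 (19.9 to 33.7), and contributed 0.809% and 15.75% of the libraries' C3 UMIs. Thinned to 2000 UMIs, 0.704% (0.283 to 1.44) of 995 sham fibroblasts and 23.15% (21.42 to 24.95) of 2242 resected fibroblasts held a C3 UMI, with 1934 and 919 cells left out. Unthinned, the shares were 1.43% and 25.31%, at median depths of 1719 and 2551 UMIs. As a class, the thinned sham share lay at the endocardial background and the resected share far above it. The log2 ratio of fibroblast C3 was 4.68 from all cells and 6.46 from thinned cells. Most of the resected value came from 1 cluster found almost only in that library. Clustered without complement genes, a cluster of 82 sham and 1038 resected cells had 588 CPM after resection and held 74.24% (72.52 to 75.90) of the class's 2620 C3 UMIs. The other 5 clusters had 34.7 to 362 CPM after resection, with ratios from 4.74 (3.37 to 6.85) to 28.1 (11.8 to 87.7). The cluster with the ratio of 4.74 had 76.4 CPM (54.1 to 104.8) in its 280 sham cells. It held 64.41% (50.87 to 76.45) of the 59 C3 UMIs of sham fibroblasts, so some sham fibroblasts already carried C3. In macrophages or monocytes C3 was 44.1 CPM in sham and 148 CPM after resection, a ratio of 3.36 (2.31 to 5.07). Their thinned shares were 5.16% (1.69 to 11.6) of 97 cells and 20.66% (17.7 to 23.8) of 702 cells, with 287 and 184 left out. The class ratio mixes unlike clusters, again formed without complement genes. One of 275 sham and 446 resected cells had 2 C3 UMIs in sham, below its floor of 6.16 CPM, and 98.8 CPM after resection. Another, of 131 and 202 cells, held 27 sham C3 UMIs and had 129 and 272 CPM. The last held 1 sham and 272 resected cells, with 165 CPM after resection. Neutrophils, few in sham, had 323 CPM and 265 CPM, and their ratio of 0.822 (0.539 to 1.32) includes 1.

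**Figure D2:**
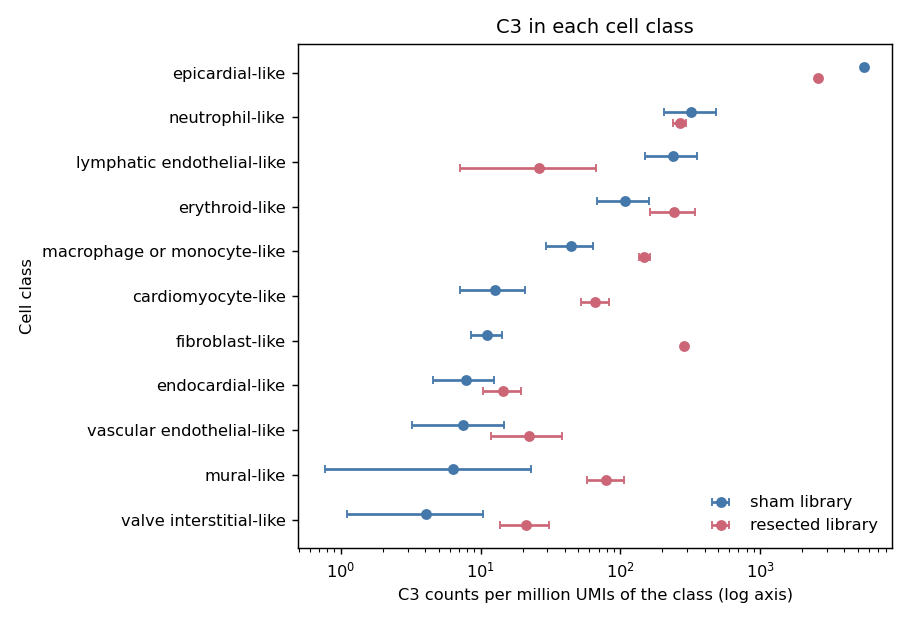
C3 in CPM, UMIs scaled to a class sum of 1000000 (log axis), per class and library, drawn as points with lines for 95% Poisson intervals that cover counting error only. Epicardial C3 lies at 5539 CPM in sham and 2577 CPM after resection, and fibroblast C3 at 11.1 and 285 CPM.

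Other complement genes were compared in the same classes. Cfb (ENSMUSG00000090231, chromosome 17, 34856374 to 34862518, minus strand) encodes factor B, which combines with C3b to form the convertase of the alternative pathway. It was higher in every main source, with 12.8 and 82.7 CPM over all cells, a ratio of 6.46 (5.61 to 7.47). Epicardial cells had 139 and 262 CPM, a ratio of 1.88 (1.61 to 2.21), fibroblasts 1.09 and 56.1 CPM, a ratio of 51.5 (23.5 to 141), and macrophages or monocytes 21.3 and 114 CPM, a ratio of 5.36 (3.16 to 9.90). The epicardial part of the library's Cfb UMIs was 86.79% in sham and 57.37% after resection. Over the complement component list, 10 of 12 measured genes were lower in the epicardial class by at least 1.5-fold and 1 was higher, with a median log2 ratio of -1.0 (-1.18 to -0.63, percentile 0.0 of random lists). In thinned cells this median was smaller in size and lay outside that interval. C4b, at 105 and 42.6 CPM, and C2, at 154 and 68.9 CPM, were among the lower ones. In fibroblasts 7 of 13 were higher and 0 lower, with a median of 0.88 (percentile 100) and 2.12 in thinned cells. C1s1, at 4.18 and 21.8 CPM, and C1ra, at 8.54 and 38.8 CPM, encode the proteases that start the classical pathway. In macrophages 5 of 11 were lower and 3 higher, with a median of -0.54 (percentile 0.7), which was 0.50 with doublets kept. Its interval of -1.14 to 1.75 held 0, so the list had no direction. There C1qa had 3815 and 1727 CPM and C1qc 2273 and 1079 CPM. The cluster led by C1qa held 270 of 384 sham and 290 of 886 resected cells of this class. C1q genes were not compared within clusters, so these CPM values also follow the mix of clusters.

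The receptors of the cleaved peptides sat on myeloid cells. C3ar1 (ENSMUSG00000040552, chromosome 6, 122847138 to 122856161, minus strand), the receptor for C3a, had 272 and 330 CPM in macrophages or monocytes, a ratio of 1.21 (1.04 to 1.43), and this class held 91.8% of C3ar1 UMIs in sham and 95.4% after resection. Thinned, 42.3% of sham and 45.0% of resected macrophages held a C3ar1 UMI. Over all cells C3ar1 was at 11.8 and 41.9 CPM, a ratio of 3.56 (3.06 to 4.17), while the class itself was 2.11 times as abundant and its cells were deeper. In epicardial cells 0 C3ar1 UMIs were counted in sham, below a floor of 2.27 CPM, and 8 after resection, at 1.61 CPM. C5ar1 (ENSMUSG00000049130, chromosome 7, 16246743 to 16259540, minus strand), the receptor for C5a, had 115.5 and 180 CPM in macrophages or monocytes, a ratio of 1.56 (1.22 to 2.00), and 154 and 150 CPM in neutrophils. Over all cells it had 5.68 and 30.5 CPM. The list of complement receptors and regulators had a median log2 ratio of 0.28 in macrophages (percentile 96.9), with 5 of 11 members higher and 3 lower by 1.5-fold. Itgam and Itgb2, the chains of complement receptor 3, had 112 and 430 CPM and 82.0 and 184 CPM, and Vsig4, a C3b receptor of resident macrophages, had 45.6 and 8.70 CPM. In epicardial cells the list's median was -0.44 (percentile 6.0) over 4 members, and in fibroblasts 0.17 over 5.

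The next comparison concerned the epicardial class itself, with 470 sham and 874 resected cells. Wt1 (ENSMUSG00000016458, chromosome 2, 105126529 to 105173616, plus strand), a transcription factor that marks the epicardium, had 262.5 and 253 CPM, a ratio of 0.964 (0.855 to 1.09) that includes 1. More of the other identity genes were lower than higher. Across the identity list 9 of 17 members were lower and 3 higher, with a median log2 ratio of -0.73 (percentile 0.0). Tcf21 had 38.6 and 10.2 CPM, Sema3d 260 and 120, Tbx18 176 and 85.2, and Gpm6a 612 and 329. These 4 were not compared by cluster. Clustered without complement genes, the epicardial cluster with most sham cells (447 and 413) had Msln at 1941 and 1947 CPM and Upk3b at 1624 and 1518. There Krt8 had 530 and 861 CPM, Krt18 982 and 1051, and Krt19 1399 and 1736. The other cluster, 23 sham and 457 resected cells, had Msln at 553.5 and Upk3b at 475.6 CPM after resection. Of the mesenchymal transition genes, 9 of 19 were higher and 0 lower, with a median of 0.56 (percentile 100) whose interval reached 0 (0.00 to 1.51). Among the higher ones were the actin-binding gene Tagln (18.1 and 107 CPM), the cadherin Cdh2 (18.1 and 72.1 CPM), S100a4 (153 and 436 CPM) and the hyaluronan receptor Cd44 (30.3 and 95.6 CPM).

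Inflammatory genes were higher in the resected epicardial cells. The cytokine and chemokine list had a median log2 ratio of 2.17 with 12 of 16 members higher and 2 lower (percentile 100), and 0.62 when members with 1 or more UMIs were included. The neutrophil attractant Cxcl5 had 1 UMI in sham and 467 CPM after resection, a ratio of 617 (111 to 24390). Cxcl1 had 62.0 and 742 CPM, a ratio of 12 (9.61 to 15.1), Cxcl2 had 6.05 and 97.6 CPM, a ratio of 16.1 (8.12 to 37.6), and the monocyte attractant Ccl2 had 88.5 and 770 CPM, a ratio of 8.70 (7.24 to 10.6). The granulocyte growth factor Csf3 had 0 UMIs in sham and 96.8 CPM after resection, at least 42.7-fold higher against the floor of 3 counts, with a lower interval bound of 34.6. The acute phase list had a median of 1.10 with 12 of 18 members higher and 0 lower (percentile 100). Its leading gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), a serum amyloid induced by inflammatory cytokines, had 251 and 4987 CPM, a ratio of 19.9 (17.8 to 22.2), and so was more abundant than C3 in the resected class. Haptoglobin (Hp) had 43.9 and 381 CPM, and the adhesion molecule Vcam1 28.7 and 253 CPM. Serpinb2, at 0 UMIs and 97.4 CPM, was at least 42.9-fold higher against the floor, with a lower interval bound of 34.8, and the injury-related gene Sprr1a had 3.03 and 91.0 CPM, a ratio of 30.1 (11.7 to 111). Interferon-stimulated genes went the other way by a small amount, with a median of -0.37 (percentile 1.8), 4 of 18 members lower and 1 higher. Ifi27l2a had 499 and 409 CPM.

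Proliferation genes were higher in resected epicardial cells, with a median log2 ratio of 1.10, 24 of 30 members higher and 0 lower (percentile 100), and 0.59 in thinned cells. The share of cells with a Mki67 UMI, a gene chosen after its values were seen, depended on depth and on the cells left out. It was 10.69% (7.22 to 15.07) and 11.26% (9.17 to 13.65) in cells thinned to 2000 UMIs, 4.04% (2.45 to 6.24) and 6.52% (4.98 to 8.37) thinned to 1000 with no cell left out, and 7.66% and 20.48% unthinned. Birc5 had 46.1 and 143 CPM, Cdc20 21.9 and 75.1, and Ccnb1 15.1 and 54.2, all of them genes of mitosis. Hypoxia and glycolysis genes had a median of 0.75 with 12 of 21 members higher and 1 lower (percentile 100). The vasodilator peptide gene Adm had 2.27 and 26.1 CPM, Eno1 128 and 313, and Ldha 219 and 498. Ndufa4l2, a hypoxia-induced mitochondrial gene, had 6.05 and 60.1 CPM, a ratio of 9.93 (4.97 to 23.2), while Txnip, which restrains glucose uptake, had 506 and 160.5 CPM, a ratio of 0.317 (0.286 to 0.352). Matrix and fibroblast activation genes had a median of 0.55 (-0.20 to 1.17), with 9 of 18 higher and 2 lower (percentile 100), and -0.07 with doublets kept. Osteopontin (Spp1) had 0 UMIs in sham and 37.8 CPM after resection, and the protease inhibitor Timp1 605 and 1366 CPM. Macrophages or monocytes of the resected library held far more Spp1, so stray RNA from them is not excluded as its source. Secreted growth factor genes went both ways, with a median of -0.40 (-0.81 to 0.02), 11 of 24 members lower and 4 higher (percentile 0.3). Among the lower ones Wnt5a had 177 and 69.9 CPM, Igf2 415 and 183, and Rspo1 357 and 179. The 12 lower genes named by rule included Cst9, at 251 and 45.6 CPM and a ratio of 0.182 (0.153 to 0.216), Slurp1, at 156 and 27.7 CPM and a ratio of 0.178 (0.142 to 0.222), the chemerin gene Rarres2, at 3002 and 1085 CPM and a ratio of 0.361 (0.347 to 0.377), and Ecrg4, at 472 and 164 CPM and a ratio of 0.348 (0.313 to 0.387).

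Lists of other cell types were read for signs of foreign RNA in this class. They cannot tell such RNA from the cells' own expression. Sarcomere genes had a median of -1.34 with 12 of 13 lower, Myl2 at 274 and 96.8 CPM. The neutrophil genes S100a8 and S100a9, named here and below for this purpose after their values were seen, had 3.03 and 43.0 CPM, a ratio of 14.2 (5.47 to 52.6), and 0 UMIs and 24.5 CPM, at least 10.8-fold higher against the floor, with a lower interval bound of 8.65. Thinned, 0.763% and 4.46% of epicardial cells held an S100a8 UMI. The resident macrophage list, which also holds genes that epicardial cells express, had -0.67, the inflammatory and repair macrophage list 0.50, the fetal cardiomyocyte list -0.39 and the angiogenesis list -0.09 with 4 of 13 members higher and 4 lower. Fatty acid oxidation had 0.14 with 3 of 16 higher and 3 lower. Haemoglobin genes had 0.78 and -1.76 with each library clustered alone, and the sex-linked list had -0.29. The class was made of 2 clusters. The first held 446 sham and 415 resected cells and was led by Msln and Upk3b. The other held 24 and 459 cells and was led by Krt8, Wnt4, Cldn3, Timp1, Sprr1a and Clu, so most resected values mix both and most sham values come from the first. A cluster found almost only in 1 library cannot be separated from that library's own preparation.

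**Figure D3:**
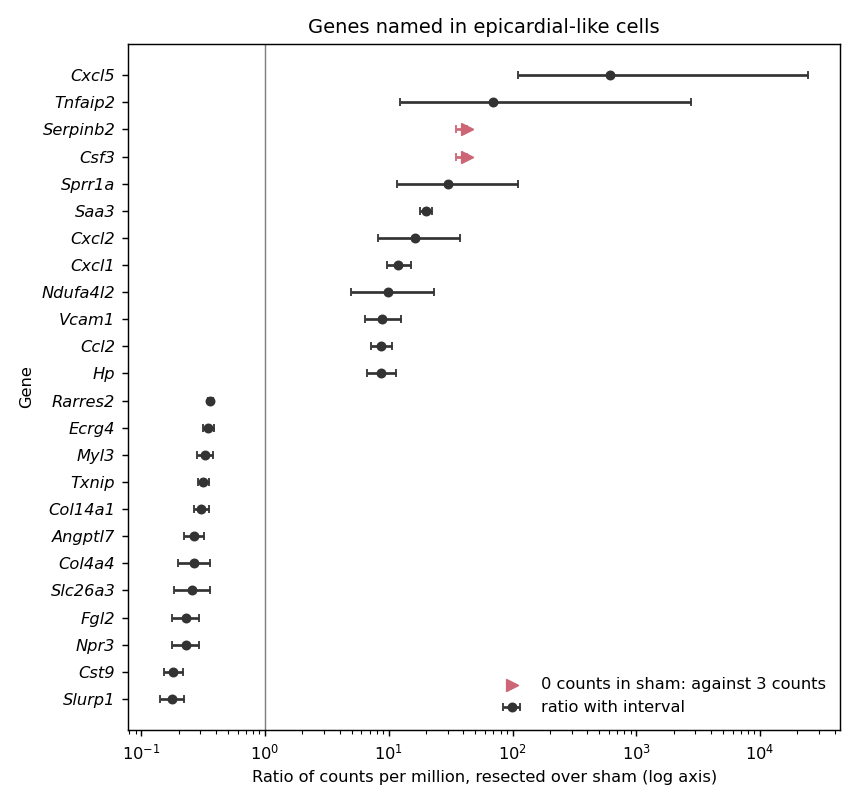
Ratio of CPM in epicardial cells, resected over sham (log axis), for the 12 higher and 12 lower genes named by rule, drawn as points with lines for 95% exact intervals that cover counting error only, and arrowheads for genes with 0 UMIs in sham, set at the ratio against the floor of 3 counts with a line to the lower interval bound. Saa3 lies at 19.9, Ccl2 at 8.70, Rarres2 at 0.361 and Slurp1 at 0.178.

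Fibroblasts were compared over 2929 sham and 3161 resected cells. Cytokine and acute phase genes were higher. The cytokine list had a median log2 ratio of 2.46, with 18 of 19 members higher and 0 lower (percentile 100), and 1.69 with doublets kept. Cxcl5 had 2.18 and 503 CPM, a ratio of 231 (132 to 447), Cxcl2 15.8 and 379 CPM, a ratio of 24.0 (19.4 to 30.0), Ccl7 10.5 and 263 CPM, and Ccl2 59.4 and 649 CPM. Csf3 had 0 UMIs in sham and 52.3 CPM after resection, at least 96.1-fold higher against the floor, with a lower interval bound of 77.8. Acute phase genes had a median of 1.73 with 14 of 18 higher and 0 lower (percentile 100). Saa3 had 0.727 and 779 CPM, a ratio of 1072 (418 to 3934), the iron-binding lipocalin Lcn2 1.09 and 224 CPM, a ratio of 206 (94.4 to 561), and Serpina3n 5.63 and 144 CPM. Interferon-stimulated genes were higher here, with a median of 0.82 and 14 of 20 members higher (percentile 100), in contrast to epicardial cells. Gbp2 had 2.54 and 12.7 CPM and Irf7 7.26 and 17.6 CPM. The difference between the classes was not tested.

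Matrix genes of fibroblasts differed little as a list, with a median of 0.13 and 4 of 21 members higher (percentile 99.7). Timp1 was at 60.1 and 462 CPM, Spp1 at 1.09 and 22.8, and the collagen crosslinking enzyme Lox at 112 and 171. For Spp1, stray macrophage RNA is not excluded here either. Hypoxia and glycolysis genes had a median of 0.44 (percentile 100), with Slc2a1 at 4.18 and 15.3 CPM and Hk2 at 18.4 and 48.4 CPM. Growth factors had -0.11, with the chemokine Cxcl12 higher at 32.9 and 86.4 CPM and midkine (Mdk) lower at 654 and 444 CPM. Proliferation genes were lower by an amount that depended on which cells were counted, with a median of -0.18, all 30 members within 1.5-fold (percentile 0.2), and -0.77 in thinned cells. Thinning keeps the proportions within a cell, so the values at 2000 UMIs also reflect the shallower cells left out, most of them sham. The cluster of cycling fibroblasts had a median of 2771 UMIs. Thinned to 2000 UMIs, 33.27% (30.34 to 36.29) of sham and 19.49% (17.87 to 21.19) of resected fibroblasts held a Mki67 UMI, with 1934 and 919 cells left out. The shares were 12.33% and 10.38% thinned to 1000 with no cell left out, and 18.68% and 18.06% unthinned. Mki67 had 261 and 215 CPM, and the histone gene Hist1h1b 860 and 448.5 CPM, a ratio of 0.522 (0.5 to 0.544). The mesenchymal transition list had 0.09, epicardial identity 0.04, fatty acid oxidation -0.08 and angiogenesis 0.17. The remaining lower genes by rule were mostly sarcomere genes, such as Myl3 at a ratio of 0.538 and Tnni3 at 0.532, and the sarcomere list had -0.61 with 10 of 16 lower. Myeloid genes were higher in this class, with S100a8 at 5.63 and 35.4 CPM, a ratio of 6.29 (4.35 to 9.42), and S100a9 at 7.45 and 30.6 CPM. The inflammatory and repair macrophage list had 0.21 (percentile 99.8) and the resident macrophage list 0.38 (percentile 99.6), with an interval of -0.32 to 0.83. Fibroblasts fell into 5 clusters. The one led by Cxcl5, Serpina3g, Ptx3, Ccl7 and Ccl2 held 16 sham and 786 resected cells, while the others held 1235 and 732, 816 and 669, 287 and 468, and, for cycling cells, 575 and 506.

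Macrophages and monocytes, 384 sham and 886 resected cells, were compared for the balance of resident and recruited states. The median of all expressed genes was -0.16 in this class, and list medians are to be read against it. Resident macrophage genes were lower, with a median log2 ratio of -0.94, 10 of 12 members lower and 1 higher (percentile 0.0). Lyve1 had 141 and 27.3 CPM, a ratio of 0.193 (0.143 to 0.261), the mannose receptor Mrc1 618 and 216, and the growth arrest factor Gas6 71.4 and 20.7. Inflammatory and repair macrophage genes went both ways, with a median of 1.12 (-0.37 to 1.84), 13 of 21 members higher and 4 lower (percentile 100). Arginase 1 (Arg1) had 4.56 and 564 CPM, a ratio of 124 (42.3 to 600), Spp1 299 and 8105 CPM, a ratio of 27.1 (23.5 to 31.3), and Gpnmb 69.9 and 378 CPM. The members that were lower, named after their values were seen, were Plac8, Apoe, Ccr2 and Ly6c2, of which Plac8, Ccr2 and Ly6c2 mark blood monocytes. With each library clustered alone the medians were -1.57 and 1.87. Saa3 had 39.5 and 20180 CPM, a ratio of 511 (349 to 782), the scavenger receptor Marco a ratio of 219 (93.9 to 676), and Acod1, which makes itaconate, a ratio of 37.7 (18.3 to 94.0). The interleukin 1 antagonist Il1rn had 1.52 and 134 CPM, a ratio of 88.3 (15.8 to 3494).

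The acute phase list of macrophages had a median of 1.04, with 14 of 20 higher (percentile 100), and the cytokine list 0.97, with 15 of 24 higher and 0 lower (percentile 100). Hypoxia and glycolysis genes had a median of 1.27, with 18 of 21 higher and 0 lower (percentile 100). Slc2a1 had 12.2 and 83.4 CPM, Hmox1, the haem-degrading enzyme, 245 and 873, and Ldha 314.5 and 1057. Interferon-stimulated genes were lower, with a median of -0.71 and 12 of 19 lower (percentile 0.0), Bst2 at 327 and 162 CPM. Proliferation genes had -0.37, 3 of 29 higher and 8 lower (percentile 4.0), and -1.02 in thinned cells. Fatty acid oxidation had -0.21, growth factors -0.21, matrix genes 0.10 and angiogenesis genes -0.56. The mesenchymal transition list had -0.03, and 0.13 after median scaling. Sarcomere genes had -1.43 (-1.98 to 0.10), with 11 of 15 lower and 2 higher. Fetal cardiomyocyte genes (-1.14) and haemoglobin (-1.91) were lower, and so were granule genes of immature granulocytes, with Elane at 97.2 and 1.2 CPM and Mpo at 54.7 and 2.40 CPM. Granulocyte-lineage cells inside the sham class are therefore not excluded, and would affect its ratios, C3 included. Formed without complement genes, its cluster of 131 sham cells had C3ar1 at 28.7 CPM in sham, against 355 in the cluster of 275 sham cells. The clusters of this class differed between the libraries. One led by C1qa and Mrc1 held 270 and 290 cells, one led by Marco, Saa3 and Arg1 held 106 and 437, and one led by Spp1, Gpnmb and Lgals3 held 8 and 159. Neutrophils came from 1 cluster of 37 and 453 cells, too few in sham for list comparisons.

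Vascular endothelial cells, 454 sham and 175 resected, were compared for activation and vessel growth. Activation genes were higher. The cytokine list had a median log2 ratio of 1.98, with all 9 measured members higher by at least 1.5-fold (percentile 100), Cxcl2 at 20.6 and 202 CPM and Cxcl10 at 27.2 and 87.4 CPM. The acute phase list had 1.36, with 12 of 16 higher and 0 lower (percentile 100), and 0.51 over members with 100 or more UMIs, 0.53 as the mean of per-cell values and 0.59 in thinned cells. Lrg1 had 8.44 and 89.1 CPM. P-selectin (Selp), which tethers leukocytes to the vessel wall, had 15 and 219 CPM, a ratio of 14.6 (8.67 to 26.4). The angiogenesis list had a median of -0.15, with 2 of 17 higher and 1 lower (percentile 4.0), and 0.05 with the stricter filter. Plvap was higher, at 42.2 and 108 CPM, and the tip-cell peptide Apln lower, at 100 and 51.4 CPM, while Kdr, the main receptor for VEGF, had 872 and 687 CPM. Proliferation (-0.15), hypoxia (0.08), fatty acid oxidation (-0.08), interferon-stimulated (0.13), growth factor (0.19) and matrix (0.20) lists had intervals that held 0, with 6 of 15 matrix genes higher and 2 lower. Mesenchymal transition genes were slightly higher, at 0.20 (0.06 to 0.74) with 4 of 15 higher and 1 lower (percentile 96.4). Neutrophil genes were among the highest by ratio in this class, with S100a8 at 2.81 and 394 CPM, a ratio of 140 (47.3 to 684), and S100a9 at a ratio of 45.3 (18.9 to 142). In the main run neutrophils were 11.2 times as abundant in that library, and less so with each library clustered alone. Macrophage genes were higher too, with 0.91 for the resident list over 5 members (percentile 100) and 0.47 for the inflammatory and repair list over 12 (percentile 100). Sarcomere genes had a median of -1.49 with 12 of 13 lower, and haemoglobin -2.63 over 3 genes.

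Cardiomyocytes, 542 sham and 474 resected cells at median depths of 1496.5 and 1552 UMIs, were compared for sarcomere maturity, stress and cell cycle. Clusters with Nppa, Myl7, Myl4 and Sln among their leading genes held 74 sham and 31 resected cells, and 124 and 133 cells. The fetal list holds Nppa, Myl4 and Myl7, so its values mix these clusters with the rest of the class. The mature sarcomere list had a median log2 ratio of -0.02 with all 17 members within 1.5-fold (percentile 3.7). The members with the clearest difference were lower, with Ttn at 7007 and 5118 CPM, Atp2a2 at 2328 and 1740, and Ryr2 at 636 and 489. Fetal and stress genes had -0.07, with 1 of 17 higher and 1 lower (percentile 1.8). Neither list kept a direction under the alternatives. The sarcomere median was 0.17 with doublets kept and -0.60 with each library clustered alone, and the fetal median was 0.15 and -0.62 there and 0.30 with the stricter filter. Skeletal actin (Acta1) had 84.3 and 38.1 CPM, a ratio of 0.452 (0.307 to 0.654), with a log2 ratio of -1.15 that was -0.07 in thinned cells, and the atrial peptide gene Nppa 7664 and 6176 CPM. Proliferation genes had a median of 0.00 (-0.16 to 0.31), with 4 of 25 higher and 2 lower (percentile 52.8), so the list had no direction. Whether depth limited this was not tested. Hypoxia and glycolysis genes were slightly higher, at 0.23 with 3 of 17 higher (percentile 99.3), Tpi1 at 819 and 974 CPM and Pkm at 596 and 718. With each library clustered alone this median was -0.07. Fatty acid oxidation had 0.15 (percentile 93.3), Acadvl at 297 and 399 CPM and Cd36 at 165 and 110. The stress metallothionein Mt1 had 312 and 562 CPM, a ratio of 1.80 (1.58 to 2.06), and the imprinted gene Dlk1 15.2 and 51.7 CPM, a ratio of 3.41 (1.98 to 6.15).

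Several of the remaining named genes in cardiomyocytes belong to other classes. Saa3 had 2 UMIs in sham and 124 CPM after resection, a ratio of 73.7 (20 to 614), Cxcl2 a ratio of 6.68 (3.78 to 12.7), and C3 12.7 and 66.2 CPM, a ratio of 5.23 (2.98 to 9.82), all of them far more abundant in epicardial cells, fibroblasts or myeloid cells of the resected library. The C3 ratio rests on a few cells, since 1.84% (0.888 to 3.37) of sham and 2.32% (1.16 to 4.11) of resected cardiomyocytes held a C3 UMI, unthinned. The capillary gene Fabp4 had 611 and 247 CPM, a ratio of 0.404 (0.350 to 0.465), in a library with fewer capillary cells. The cytokine list had 2.74 over 5 members, acute phase genes 0.24, the complement component list 0.93 over 3 members, growth factors 0.04, angiogenesis genes -0.38 and mesenchymal transition genes -0.22, which was 1.59 with each library clustered alone. The inflammatory and repair macrophage list had -0.34, which was above 0 under 4 alternatives, and haemoglobin had -4.11.

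**Figure D4:**
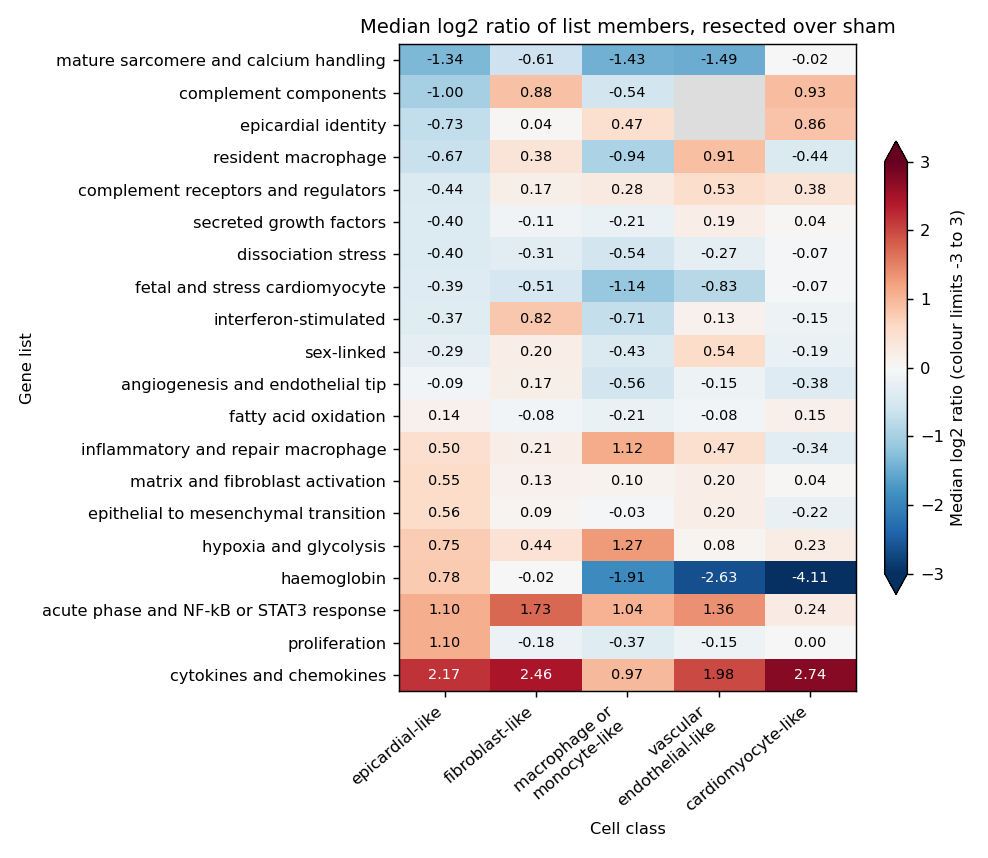
Median log2 ratio (resected over sham) of each gene list in the epicardial, fibroblast, macrophage or monocyte, vascular endothelial and cardiomyocyte classes, as coloured cells with the value printed. The cytokine list is above 0 in all 5 classes (0.97 to 2.74), and the sarcomere list lies between -0.61 and -1.49 in the 4 that are not cardiomyocytes.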

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

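The expected doublet rate in both libraries, clustering without the complement genes, macrophages and monocytes apart, and the myeloid classes together were alternatives chosen only after the results were seen. Of 412 values of named genes under other settings, 350 stayed within their counting interval and 62 moved outside it. In 0 did the sign change where the main interval excluded no difference. Apart from epicardial C3, these genes were rerun only with median scaling, without mitochondrial, ribosomal protein and haemoglobin genes in the total, as per-cell means, and in thinned cells. They were not rerun under another filter, doublet rule or clustering. Genes with 0 UMIs in a class and library were left out. A list median stayed when it lay within the 95% interval of the main median, and is called reversed when its sign changed although that interval excluded 0. Of 1346 list medians under other settings, 1232 stayed, 103 moved and 11 reversed. In all, 93 had another sign than the main value, and in 82 of these the main interval held 0, so that those lists had no settled direction. Of the class share ratios 78 stayed, 30 moved and 2 reversed. The cause was not tested for any of these, except where stated. No paired analysis was possible because each group is 1 pooled library.

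With the looser filter the share ratios were 1.53 for B lymphocytes, 2.00 for epicardial cells, 1.34 for mast cells, 4.77 for neutrophils and 2.46 for the myeloid classes together. The inflammatory and repair macrophage list in cardiomyocytes reversed to 0.12. With the stricter filter the ratios were 0.450 for cardiomyocytes, 0.747 for endocardial, 0.250 for erythroid, 1.65 for macrophages or monocytes, 1.36 for fibroblasts, 1.13 for mast cells, 4.06 for neutrophils, 0.210 for vascular endothelial cells and 1.86 for myeloid classes together, and the valve interstitial ratio reversed to 1.12. This filter kept 24.4% of sham and 50.2% of resected barcodes. Epicardial C3 had a log2 ratio of -1.01, the resident macrophage list -0.68 and the fetal list of cardiomyocytes 0.30. The haemoglobin list in epicardial cells reversed to -0.67 and the inflammatory and repair macrophage list in cardiomyocytes to 0.14.

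With all doublets kept the ratios were 0.578 for cardiomyocytes, 1.06 for fibroblasts, 1.70 for macrophages or monocytes, 7.33 for neutrophils and 2.32 for the myeloid classes together. Epicardial C3 had -0.90 and epicardial proliferation 0.62, and in cardiomyocytes the sarcomere list had 0.17 and the fetal list 0.15. The haemoglobin list in epicardial cells reversed to -0.01 and the inflammatory and repair macrophage list in cardiomyocytes to 0.19. With the expected doublet rate the ratios were 1.81 for macrophages or monocytes, 7.79 for neutrophils and 2.40 for both together. At resolution 2 the fibroblast ratio was 1.22, and without complement genes in the clustering the mural ratio was 0.940. At resolution 0.5 no result of a main comparison moved outside its counting interval.

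With each library clustered alone the ratios were 1.90 for fibroblasts, 3.48 for macrophages or monocytes, 1.87 for neutrophils and 0.695 for vascular endothelial cells, and the cardiomyocyte ratio reversed to 1.22. The inflammatory and repair list of macrophages had 1.87. In cardiomyocytes the sarcomere list had -0.60 and the fetal list -0.62, and the mesenchymal transition list (1.59), the hypoxia list (-0.07) and the inflammatory and repair macrophage list (0.83) reversed. The haemoglobin list reversed to -1.76 in epicardial and to 0.77 in vascular endothelial cells. Kept apart, macrophages had a share ratio of 1.47 and monocytes 3.76.

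Epicardial C3 had -1.04 with median scaling, -0.86 as the mean of per-cell values and -0.88 in thinned cells, so it stayed below 0 under every setting run. All of these settings are relative to a total of RNA, and C3 UMIs per cell were not among them. Thinned, the epicardial complement list had -0.61, epicardial proliferation 0.59, and the complement receptor list of vascular endothelial cells reversed to -0.15. Median scaling gave the resident macrophage list -0.78. The difference in the percent of epicardial cells with a C3 UMI, -15.7 when thinned to 2000 UMIs, was -19.6 thinned to 1000 and -7.25 with no thinning, where the deeper resected cells gain most. Depth limits the thinned values of sham cells, of which 4773 held fewer than 2000 UMIs, and class shares below 1% rest on few sham cells, as with 11 mast cells and 37 neutrophils.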

Other observations

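Classes outside the main comparisons shared the inflammatory difference between the libraries. In endocardial cells, 1009 sham and 1007 resected, the acute phase list had a median log2 ratio of 1.22 and the cytokine list 1.2, with Ccl2 at 22.6 and 106 CPM, a ratio of 4.67 (3.44 to 6.45), and Cxcl10 at 16.2 and 53.1 CPM. Their interferon-stimulated list had 0.21 (percentile 98.2), and Hspa1a, a heat shock gene, had 81.7 and 22.9 CPM. Valve interstitial cells, 630 and 576, had smaller values of 0.55 and 0.88 for the same 2 lists and lower proliferation genes (-0.45, 6 of 15 members lower and 1 higher). Their highest genes by rule were the matrix gene Thbs4, at 7.14 and 66.85 CPM, a ratio of 9.36 (4.34 to 24.0), Cldn3, at 15.3 and 50.5 CPM, a ratio of 3.30 (1.86 to 6.25), and the imprinted H19, at 231 and 484 CPM, a ratio of 2.10 (1.80 to 2.46). Cldn3 was also a leading gene of the epicardial cluster found mostly in the resected library. Mural cells, 156 and 204, had 0.80 for acute phase genes, 1.31 for cytokines and 0.63 for complement components over 5 members. There Vegfd was lower, at 89.4 and 8.79 CPM and a log2 ratio of -3.35 (-1.05 in thinned cells). Erythroid cells, 107 and 51, had 4.55 for cytokines over 5 members, 0.70 for acute phase genes with an interval that held 0 (-0.13 to 4.15), and -0.27 for haemoglobin itself. In lymphatic endothelial cells the 23 sham C3 UMIs came from 1 of 33 cells, and the 4 resected UMIs from 4 of 40 cells. C3 was at a higher CPM in mural (6.39 and 79.1 CPM), valve interstitial (4.08 and 21.2 CPM), vascular endothelial (7.50 and 22.3 CPM) and endocardial cells (7.85 and 14.4 CPM) of the resected library. The share of cells with a C3 UMI, unthinned, was at most 4.41% in these classes, in resected mural cells.

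Genes of other cell types also differed between the libraries within the classes. Sarcomere genes were lower after resection in the epicardial (-1.34), fibroblast (-0.61), vascular endothelial (-1.49), endocardial (-0.87) and valve (-1.29) classes, with -0.42 in mural cells (interval -0.97 to 0.01) and -0.05 in erythroid cells. The neutrophil gene S100a9 was higher in endocardial cells (14.3 and 52.4 CPM), mural cells (9.58 and 121 CPM) and valve interstitial cells (10.2 and 23.6 CPM), besides the epicardial, fibroblast and vascular endothelial classes. Its CPM was lower in cardiomyocytes, lymphatic endothelial cells and B lymphocytes, where the sham UMIs came from 12 of 542, 1 of 33 and 2 of 35 cells, while the share of cells with a UMI was higher in cardiomyocytes, at 2.21% (1.15 to 3.84) and 5.49% (3.61 to 7.93). Haemoglobin genes went both ways, with 3.30 in mural cells and -4.11 in cardiomyocytes. Dissociation stress genes, immediate early and heat shock genes that rise while tissue is digested, were lower in 6 of 9 classes, with the lowest median in macrophages (-0.54). The intervals held 0 in cardiomyocytes (-0.07, -0.65 to 0.09), epicardial cells (-0.40, -0.64 to 0.02) and vascular endothelial cells (-0.27, -0.42 to 0.04). In epicardial cells Fos had 1939 and 1086 CPM and Ier3, the exception among the leading members, 435 and 722.

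In the paragraphs that follow, the tests of cluster mix for epicardial and fibroblast C3, of depth and class total for epicardial C3, and of missing Xist counts, were chosen only after the result was seen. Epicardial C3, relative to the class total, was lower in the resected library by a ratio of 0.465. A different mix of the 2 epicardial clusters cannot be the whole cause, since within the cluster that held most sham cells, formed without complement genes, the ratio was still 0.712 (0.690 to 0.735). The distance between these values leaves cluster mix a large part. A class total taken up by some other genes is argued against by a log2 ratio of -1.04 with median scaling. Thinning keeps the proportions within a cell, so the -0.88 in thinned cells cannot decide on depth. Both values are relative, so neither could show a rise of all RNA per cell. Epicardial cells had medians of 2106.5 UMIs in sham and 4613.5 after resection. The cluster that held most sham cells had 7201 C3 UMIs in 447 sham and 8287 in 413 resected cells, so the count per cell was not lower there. Sex of the pools is argued against by a ratio of 0.438 (0.420 to 0.458) against sham cells with a Y-linked UMI and no Xist UMI. A rise of all RNA per cell therefore stays open. So do the surgery, a difference between litters or pools, and dissociation, which confound each other in a design of 1 library per group.

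Fibroblast C3 was higher in the resected library by a ratio of 25.7, and by 11.8 (5.00 to 34.1) within the cluster that held most sham cells, formed without complement genes, so that cluster mix is not the whole cause but remains a part, with 74.24% of resected C3 UMIs in 1 cluster. Free epicardial RNA would carry Msln and Upk3b, the epicardial marker genes, in proportion, yet resected fibroblasts had 55.9 C3 UMIs per UMI of these genes against 1.27 in epicardial cells, 44.2 times as many (33.1 to 60.2). Epicardial cells or doublets inside the class are argued against as well, since 1.35% (0.544 to 2.76) of C3-positive fibroblasts held a UMI of either gene, close to 0.871% of C3-negative ones. Sex is argued against by a ratio of 26.4 (14.7 to 52.9) to sham fibroblasts with a Y-linked and no Xist UMI. Fibroblasts may therefore be a second source of C3 after resection, a hypothesis from these same libraries, with pool and preparation untested. A cluster of 280 sham fibroblasts already had 76.4 CPM, so such a source would not be confined to the resected library.

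Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254, minus strand), had 2132 UMIs in the sham and 0 in the resected library. Hearts of different sex in the 2 pools would give this, and the sham library does look like a mix of sexes. Among thinned sham cells, 3.86% (2.26 to 6.10) of the 441 with a Xist UMI held a Y-linked UMI against 21.6% (20 to 23.3) of those without, with 4773 shallower cells left out. That value is measured within the sham library and would be the same if Xist counts were missing from the resected matrix. Over all thinned cells, 18.9% (17.5 to 20.4) of sham and 21.2% (20.2 to 22.3) of resected cells held a Y-linked UMI. These intervals overlap only at their ends, which does not show that the shares are equal. The resected share also lay close to the 21.6% of sham cells without a Xist UMI. The Y-linked ratio was above 1 in 7 of 9 classes, with an interval wholly above 1 in 5 of them, as in fibroblasts (1.29, 1.17 to 1.42), and wholly below 1 in 0, which goes with a more male resected pool, yet the 2 readings cannot be told apart, because pools of mixed-sex littermates can differ in their share of males whether or not Xist counts are missing.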
